A study of Macaca mulatta with 4 samples.

How the data were processed

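RNA was measured in rhesus monkey ESCs and NPCs. Total RNA was extracted with Trizol and sequenced on the BGISEQ-500 platform, per the labels' protocols. Per the labels, reads were mapped to the UCSC rhesus assembly named Rhesus8 with up to 2 mismatches, reads per gene were counted with featureCounts at default settings, and genes with more than 10 summed reads over all samples were kept. The aligner was STAR 2.4, per the submitters' processing notes. The authors deposited FPKM values, given to 2 decimals, in a table of 23697 genes with NCBI gene IDs and symbols. How FPKM was computed from the counts is not given in the sources used here. Strand was not stated, so overlapping and antisense genes cannot be told apart.

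Columns were assigned to samples by the sample description that starts each column name. 3 columns matched a sample, and 1 column of sample values matched none and was not used in any step. The haploid NPC sample was therefore not analysed here, and neither were the planned comparisons that need it: NPC against ESC in haploid cells, haploid against diploid in NPCs, and the agreement and difference between these. Filters planned over 4 libraries were applied to the mean of the 3 used. Each group held 1 library, so no test between groups was possible, and genes were counted by a fixed size of difference.

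FPKM values were used as deposited, without rescaling. The log2 ratio of 2 libraries was taken on FPKM plus 1, among 14474 genes with a mean of at least 1 FPKM, and genes with a ratio of at least 4-fold (2 on the log2 scale) were counted in each direction. The column sums of FPKM were 568734 in diploid ESCs, 492324 in haploid ESCs and 600215 in diploid NPCs. Read totals are not given in the sources used here. Relative depth was estimated from genes with values from 0.15 to 0.6 FPKM in both libraries: the most frequent ratio between 2 libraries is the ratio of what 1 read is worth in each, from 1270 genes for the haploid ESC and 883 genes for the NPC library against the diploid ESC library.

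41 gene lists were fixed before the data were examined, with 608 distinct symbols, of which 591 were found, by the symbol in the table or by the symbol that the T2T-MMU8v2.0 gene table gives to the same gene ID. That table holds 19875 of the gene IDs. It is another assembly than the one used for mapping, so only its names, chromosome assignments and gene order were used, and gene spans only to rank genes by length. The median ratio of each list with at least 5 measured members was placed among the medians of 10000 random lists matched on mean log2 value in 20 bins of equal gene number; the percentile describes these libraries and is no test. Of 37 lists with a percentile, 17 in the NPC comparison and 13 in the ploidy comparison lay below 2.5 or above 97.5. About 5% of lists of independently drawn genes would by chance. Members of a list can vary together and some genes are in several lists, so an excess over 5% is no test either.

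Genes were named by a rule also set beforehand: list members with the largest ratios, POU5F1, NANOG, SOX2, PAX6, NES, SOX1, XIST and imprinted genes whatever their values, and the 10 highest and 10 lowest ratios of each comparison among genes with a symbol, a mean of at least 1 FPKM and at least 10 FPKM in the highest library. The planned ranking by the smaller ratio of both ploidies used the diploid ratio alone, and the 5 genes with the highest values in each library were also taken. In diploid ESCs these were EEF1A1, LOC702809, ACTG1, ACTB and RPL41, in haploid ESCs LOC100499546, EEF1A1, ACTB, TMSB4X and ACTG1, and in NPCs TMSB4X, LOC702809, TMSB10, LOC106998994 and RPL41; the highest value was that of TMSB4X in NPCs, at 10455 FPKM. Other genes were named after their values were seen where a list's exception is given.

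Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The scripts were tested on simulated data, with noise of SD 0.5 on the log2 scale and 50 genes changed at each size among 14516, for the haploid against diploid ESC comparison. The changed genes were drawn from those with a mean of at least 5 FPKM, and the noise held no read sampling. Of genes changed 8-fold, 90.0% passed the 4-fold threshold, of those changed 16-fold 98.0% and of those changed exactly 4-fold 36.0%, against 0.00699% of unchanged genes. The SD of the real log2 ratios in that comparison was 0.862, so these shares check the scripts and are not error rates of the data. Of 200 unchanged lists of 12 genes, 6.0% lay outside percentiles 2.5 to 97.5. Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, trimmed mean (TMM) factors, rescaling to a sum of 1000000 (TPM), thresholds of 2-fold and 8-fold and genes with a symbol alone. The haploid ESC library in place of the diploid one was added after seeing the data.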

Results

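Gene expression was measured by RNA sequencing in embryonic stem cells (ESCs) and neural progenitor cells (NPCs) of the rhesus monkey, Macaca mulatta. ESCs are pluripotent cells grown from early embryos, and NPCs are dividing precursors of neurons and glia. The series is about haploid NPCs, which carry a single set of chromosomes, and their use in mutation screens, including screens for genes that neural toxicants act on. It has 4 samples, and 3 of them were compared here: diploid ESCs, haploid ESCs and diploid NPCs, with 1 library each. The haploid NPC sample was not analysed here. Values are FPKM, fragments per kilobase of transcript scaled to library size, for 23697 genes, of which 14474 had a mean of at least 1 FPKM. The diploid ESC library had 13721 genes at 1 FPKM or more, the haploid ESC library 13147 and the diploid NPC library 14022. Judged from the steps between low values, the haploid ESC library had 95.3% and the NPC library 78.5% of the depth of the diploid ESC library, so values near 0 are coarsest in NPCs. Across genes, which are not independent replicates, the log2 values of the 2 ESC libraries correlated with r = 0.905, against r = 0.741 between diploid ESCs and diploid NPCs and r = 0.675 between haploid ESCs and diploid NPCs. With 1 library per group, no difference given here has a replicate check, and no p-value or test between groups was computed. Log2 ratios are of FPKM plus 1, which understates the differences of genes with low values.

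The comparison of diploid NPCs with diploid ESCs asks how the progenitors differ from the stem cells. Most pluripotency transcripts that were abundant in ESCs were almost absent from diploid NPCs. Exceptions were PRDM14, at 102 FPKM in diploid ESCs and 7.93 FPKM in diploid NPCs, and USP44, at 28.8 and 7.05 FPKM, among others. POU5F1, the pluripotency factor also known as OCT4, stood at 1859 FPKM in diploid ESCs and 1.5 FPKM in diploid NPCs, and NANOG at 77.1 and 0.47 FPKM. NPCs instead carried transcripts of neural progenitors and of the midbrain and hindbrain. FABP7, a fatty acid binding protein of radial glia, stood at 0.86 FPKM in diploid ESCs, 6 FPKM in haploid ESCs and 403 FPKM in NPCs. EN1, a transcription factor of the midbrain-hindbrain boundary, was at 0.24 FPKM in diploid ESCs and 41.7 FPKM in NPCs. Of the 14474 genes, 1198 were at least 4-fold higher in NPCs and 885 at least 4-fold lower.

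The 10 genes with the highest ratios in NPCs were PTN, FABP7, CRH, ACAT2, POU3F2, C6H5orf38, CNPY1, PAX8, NR2F1 and NKX6-2. PTN (NCBI gene 709496), which encodes the secreted growth factor pleiotrophin, stood at 10.2 FPKM in diploid ESCs, 32.9 FPKM in haploid ESCs and 2667 FPKM in NPCs, a log2 ratio of 7.89 against diploid ESCs. CRH, the corticotropin releasing hormone, was at 0.11 FPKM in diploid ESCs and 191 FPKM in NPCs, and ACAT2 at 0.04 and 101 FPKM. The neural transcription factor POU3F2 was at 0.04 FPKM in diploid ESCs and 81.6 FPKM in NPCs, NR2F1 at 0.1 and 63.1 FPKM, and NKX6-2 at 0.24 and 70.6 FPKM. CNPY1 stood at 0.15 and 71.9 FPKM, PAX8 at 0.05 and 63.0 FPKM, and C6H5orf38 at 0.96 and 145 FPKM. The 10 genes with the lowest ratios were POU5F1, CER1, L1TD1, DPPA4, LIN28A, FGF17, CLDN6, FOSB, SLC2A3 and GSC. POU5F1 (NCBI gene 714760) had a log2 ratio of -9.54. The RNA binding protein LIN28A was at 257 FPKM in diploid ESCs and 0.67 FPKM in NPCs, L1TD1 at 212 and 0.15 FPKM and DPPA4 at 187 and 0.18 FPKM. The glucose transporter SLC2A3 was at 423 and 4.96 FPKM, the tight junction gene CLDN6 at 609 and 4.68 FPKM, and the immediate early gene FOSB at 82.9 and 0.16 FPKM. CER1, FGF17 and GSC, genes of the mesendoderm, were also lower in haploid than in diploid ESCs: CER1 stood at 663 FPKM in diploid ESCs, 37.6 FPKM in haploid ESCs and 0.26 FPKM in NPCs, FGF17 at 207, 17.3 and 0.68 FPKM, and GSC at 68.6, 4.8 and 0.11 FPKM.

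Of the 16 measured genes of the pluripotency list, 15 were at least 4-fold lower in NPCs and none was higher, with a median log2 ratio of -5.39, below all 10000 random lists matched on expression. ZFP42 stood at 49.8 FPKM in diploid ESCs and 0.23 FPKM in NPCs, and DNMT3B, a DNA methyltransferase, at 391 and 8.23 FPKM. SOX2, which both cell types use, was at 149 FPKM in diploid ESCs, 161 FPKM in haploid ESCs and 109 FPKM in NPCs. The Nodal pathway list had 5 of 7 measured members at least 4-fold lower and a median of -3.58. All 8 measured endoderm genes were lower in NPCs than in diploid ESCs, 6 of them at least 4-fold, with a median of -4.16, and 10 of 11 epithelial genes were at least 4-fold lower, with a median of -3.73. Most of these transcripts were also lower in haploid than in diploid ESCs, 7 of the 8 endoderm and 8 of the 11 epithelial genes by at least 4-fold, while CLDN6 stood at 316 FPKM and OCLN at 16.2 FPKM in haploid ESCs. Against haploid ESCs in place of diploid ESCs, a comparison chosen after seeing the data, the NPC medians were -0.31 for endoderm and -0.55 for epithelial genes, whereas the pluripotency median was -4.80. CDH1, the epithelial cadherin, went its own way within its list, at 17.1 FPKM in diploid ESCs, 1.5 FPKM in haploid ESCs and 23.6 FPKM in NPCs.

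The neural progenitor list had 7 of 17 measured members at least 4-fold higher in NPCs and none at least 4-fold lower, with a median of 1.70, at percentile 100 of random lists. SOX1 stood at 0.09 FPKM in diploid ESCs and 18.2 FPKM in NPCs, ZIC1 at 0.02 and 12.5 FPKM, and the intermediate filament gene VIM at 195 and 1101 FPKM. PAX6 was low throughout, at 0.26 FPKM in both ESC libraries and 3.68 FPKM in NPCs, and NES, the nestin gene, was similar in all 3, at 253, 266 and 280 FPKM in diploid ESCs, haploid ESCs and NPCs. The median was 0.34 among genes with a mean of at least 5 FPKM and 0.94 without a filter, and against haploid ESCs it was 0.072; SOX3, CDH2, GPM6A and PLAGL1 were higher in haploid than in diploid ESCs. Regional genes went both ways within the midbrain list, and most hindbrain and spinal cord genes were higher in NPCs. EN1, EN2 and PAX8 made up the 3 of 5 measured midbrain genes that were at least 4-fold higher, with EN2 at 0.02 FPKM in diploid ESCs and 48.3 FPKM in NPCs, while FOXA2 and FGF8 were at least 4-fold lower; the other 5 of the 10 midbrain genes had a mean below 1 FPKM, and without a filter the median was 0.14. FOXA2 was low in haploid ESCs too, at 0.3 FPKM against 1.12 FPKM in NPCs. GBX2, a hindbrain factor, stood at 1.26 and 109 FPKM. The hindbrain and spinal cord list had 9 of 11 measured members at least 2-fold higher in NPCs, with a median of 1.93. That median was 1.06 without a filter and 4.14 among genes with a mean of at least 5 FPKM. EGR2 was lower, at 14.9 FPKM in diploid ESCs and 0.34 FPKM in NPCs. HOXB9 was at 0.22 FPKM in diploid ESCs and 20.5 FPKM in NPCs, and HOXB7 at 0.09 and 8.39 FPKM. The forebrain gene EMX2 was at 0.26 FPKM in NPCs, and OTX2 was at 112 FPKM in diploid ESCs and 6.14 FPKM in NPCs.

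Neuron genes were higher in NPCs for 13 of 15 measured members, 7 of them at least 4-fold, with a median of 1.59. The neuronal tubulin TUBB3 stood at 25.9 FPKM in diploid ESCs and 245 FPKM in NPCs, GAP43 at 17.0 and 292 FPKM, NEFM at 6.06 and 133 FPKM and ELAVL3 at 0.27 and 28.5 FPKM. RBFOX3 and SYT1 went the other way: RBFOX3 stood at 5.85 FPKM in diploid ESCs, 0.23 FPKM in haploid ESCs and 0.45 FPKM in NPCs, and SYT1 at 19.3, 17.1 and 7.65 FPKM. Of 9 measured glial genes, S100B and SLC1A3 were at least 4-fold higher, S100B standing at 0.23 FPKM in diploid ESCs and 39.5 FPKM in NPCs, and the list as a group had a median of 0.31 at percentile 69.7.

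Among metabolic and stress genes, all 14 genes of the endoplasmic reticulum and amino acid stress list were lower in NPCs than in diploid ESCs, 5 of them at least 4-fold, with a median of -1.83. ATF3 stood at 46.5 and 1.43 FPKM, TRIB3 at 26.1 and 1.65 FPKM, and ASNS, asparagine synthetase, at 124 and 18.9 FPKM. Against haploid ESCs the median of this list was -0.96 and TRIB3 was not lower in NPCs, at 1.35 FPKM in haploid ESCs. Of 24 hypoxia and glycolysis genes, 7 were at least 4-fold lower and the median was -0.90, with VEGFA at 39.0 FPKM in diploid ESCs and 4.86 FPKM in NPCs and HK2 at 20.8 and 2.75 FPKM; against haploid ESCs the median was -0.29. Antioxidant and xenobiotic genes had a median of -1.44, and GCLC, which makes glutathione, stood at 40.0 and 2.05 FPKM. The oxidative phosphorylation list had a median of 0.62, at percentile 99.8, with 7 of 27 members at least 2-fold higher, among them COX6B1 at 399 FPKM in diploid ESCs and 904 FPKM in NPCs. SDHC, UQCRC2 and NDUFS1 were at least 2-fold lower, SDHC standing at 111 and 28.8 FPKM, and 9 members were lower in all. The cholesterol synthesis list had a median of 0.72, with FDPS at 113 and 362 FPKM. ID2 and ID3, targets of BMP signalling, were at 10.2 and 20.1 FPKM in diploid ESCs and 151 and 212 FPKM in NPCs. BMP4 went the other way, at 5.26 and 0.13 FPKM, and the BMP list as a whole had a median of 0.69 at percentile 92.1, inside the range of random lists.

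**Figure D1:**
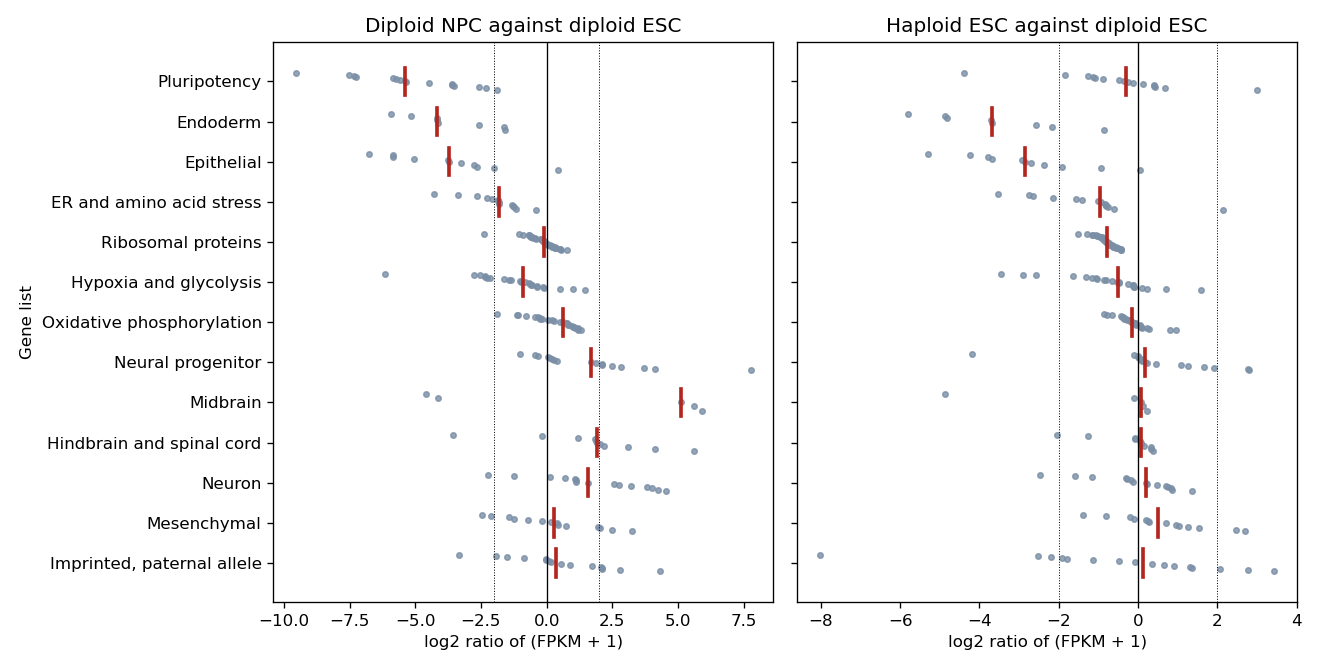
Log2 ratio of FPKM plus 1 for each measured member of 13 gene lists, for diploid NPCs against diploid ESCs on the left and haploid against diploid ESCs on the right, with 1 library per group. Points are genes, red bars are list medians and dotted lines mark a 4-fold difference; the pluripotency median is -5.39 on the left and -0.31 on the right, and the endoderm medians are -4.16 and -3.69.

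The comparison of haploid with diploid ESCs asks whether the stem cells differ with the number of chromosome sets. Several pluripotency transcripts differed by less than 2-fold, with POU5F1 at 1859 FPKM in diploid and 1332 FPKM in haploid ESCs, NANOG at 77.1 and 103 FPKM and LIN28A at 257 and 281 FPKM. Endoderm and epithelial transcripts were much lower in the haploid library: SOX17, an endoderm transcription factor, stood at 60.4 FPKM in diploid and 0.1 FPKM in haploid ESCs, and the tight junction gene CLDN7 at 55.9 and 0.46 FPKM. Fewer genes differed than between NPCs and ESCs, 151 of 14474 being at least 4-fold higher in haploid ESCs and 366 at least 4-fold lower. Higher genes made up 29.2% of these calls, and 40.3% when each library was rescaled to a sum of 1000000, with 291 higher and 431 lower. The ploidies also differ in the embryonic day their labels give, E2.5 for haploid and E3.5 for diploid samples.

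The lowest ratio in haploid ESCs was that of SNURF (NCBI gene 711028), whose transcript also encodes SNRPN and which is expressed from the paternal allele, at 473 FPKM in diploid ESCs, 0.82 FPKM in haploid ESCs and 166 FPKM in NPCs, a log2 ratio of -8.02. It was followed by SPP1, SOX17, EID1, CLDN7, FOXA2, DPRX, HHEX, CYP26A1 and LUZP6. SPP1, the secreted phosphoprotein osteopontin, stood at 3071 FPKM in diploid and 26.8 FPKM in haploid ESCs, EID1 at 58.8 and 0.26 FPKM, and CYP26A1, which breaks down retinoic acid, at 55.9 and 1.37 FPKM. DPRX, at 27.7 FPKM in diploid ESCs, was listed at 0 in haploid ESCs. So was LUZP6, at 22.6 FPKM in diploid ESCs, whose value is uncertain because it shares transcripts with MTPN. The 10 highest ratios were those of GLIPR1, SRSF10, SHOX, CTHRC1, TPTE2, RANGRF, C2H3orf14, SOHLH2, HTATIP2 and PEG3. GLIPR1 (NCBI gene 718956) stood at 2.59 FPKM in diploid ESCs, 99.3 FPKM in haploid ESCs and 3.84 FPKM in NPCs, a log2 ratio of 4.80. SHOX was at 0.41 FPKM in diploid and 19.4 FPKM in haploid ESCs, CTHRC1 at 0.67 and 21.5 FPKM, and the germ cell factor SOHLH2 at 2.22 and 37.7 FPKM. TPTE2 stood at 0.11 and 13.9 FPKM, RANGRF at 0.14 and 14.0 FPKM, C2H3orf14 at 0.71 and 20.6 FPKM and HTATIP2 at 0.62 and 16.9 FPKM. The SRSF10 row, at 16.5 FPKM in haploid ESCs and listed at 0 in the other libraries, is uncertain, since 2 rows of the table carry this symbol.

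Of 8 measured endoderm genes, 7 were at least 4-fold lower in haploid ESCs, and the list median was -3.69, below all 10000 random lists. FOXA2 stood at 36.7 FPKM in diploid and 0.3 FPKM in haploid ESCs, HHEX at 37.2 and 0.36 FPKM, the chemokine receptor CXCR4 at 112 and 7.68 FPKM and GATA6 at 18.1 and 3.27 FPKM. Of 11 epithelial genes, 8 were at least 4-fold lower, with a median of -2.86. EPCAM was at 150 and 22.2 FPKM and the splicing regulator ESRP1 at 34.6 and 1.77 FPKM, while OCLN was at 15.7 and 16.2 FPKM. Mesenchymal genes had a median of 0.50, at percentile 99.8, or 97.2 among lists matched on gene length as well, inside the central 95%, with the repressors of epithelial genes ZEB1 and ZEB2 at 1.4 and 0.58 FPKM in diploid and 14.5 and 7.73 FPKM in haploid ESCs. The fibroblast list, which covers possible feeder cells, had a median of 0.56, with ACTA2 at 17.8 and 123 FPKM and COL3A1 at 13.1 and 61.1 FPKM, while COL1A1 was at 235 and 206 FPKM.

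The endoplasmic reticulum and amino acid stress list was lower in haploid ESCs for 13 of 14 members, 4 of them at least 4-fold, with a median of -0.97. TRIB3 stood at 26.1 and 1.35 FPKM, ATF3 at 46.5 and 6.05 FPKM and DDIT4 at 66.3 and 9.65 FPKM, while CHAC1 was higher in haploid ESCs, at 0.32 and 4.88 FPKM. All 43 measured ribosomal protein genes were lower in haploid ESCs, with ratios from -1.52 to -0.42 and a median of -0.78. Ratios in this comparison were lower for shorter genes across all genes (Spearman rho 0.281 with gene length), and random lists matched on expression and gene length, a matching chosen after seeing the data, had a median of -0.36, so the ribosomal median lay 0.42 below them, at percentile 0. None of them reached 4-fold, and RPLP1 stood at 2707 FPKM in diploid and 946 FPKM in haploid ESCs. Of 24 hypoxia and glycolysis genes, 3 were at least 4-fold lower and the median was -0.51, with the vasodilator gene ADM at 17.6 and 0.69 FPKM, while LDHA was at 71.1 and 215 FPKM. The mitosis list had a median of 0.37, at percentile 99.9, with 15 of 18 members higher and none at least 2-fold, and MKI67 stood at 36.9 and 54.2 FPKM. Genes of BMP signalling had a median of 0.68, with BMP4 at 5.26 and 18.4 FPKM and BMP2 at 8.14 and 0.28 FPKM.

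The pluripotency list had a median of -0.31 in haploid against diploid ESCs, at percentile 2.7, with 1 of 16 members at least 4-fold higher, 1 at least 4-fold lower and 5 at least 2-fold lower. The 5 were UTF1, DPPA2, DNMT3B, at 391 and 109 FPKM, PRDM14, at 102 and 42.2 FPKM, and ZFP42, at 49.8 and 22.7 FPKM. GDF3 stood at 3.99 FPKM in diploid and 39.1 FPKM in haploid ESCs, and UTF1 at 25.2 and 0.25 FPKM. KLF5, listed with the naive state, was at 33.4 and 2.13 FPKM. The neural progenitor list had a median of 0.17 at percentile 90.0. Of its 17 measured members, 13 were higher in haploid ESCs, 6 of them at least 2-fold, and 1 was at least 2-fold lower. That member, SOX21, stood at 28.8 FPKM in diploid ESCs, 0.63 FPKM in haploid ESCs and 30.1 FPKM in NPCs.

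**Figure D2:**
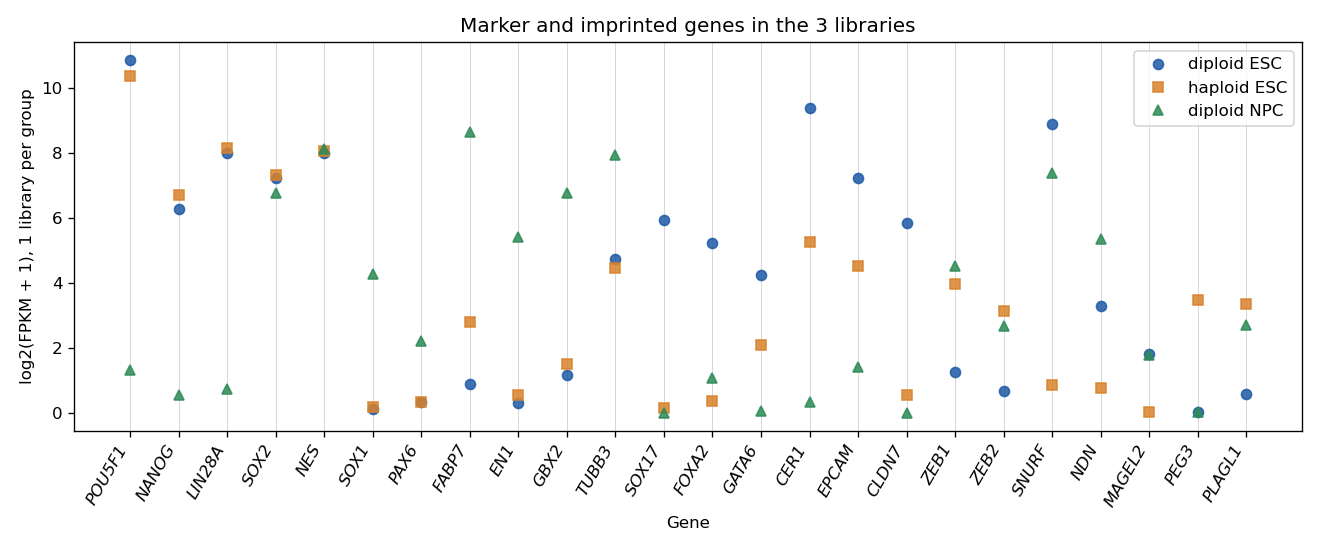
Log2 of FPKM plus 1 for 24 marker and imprinted genes in the diploid ESC, haploid ESC and diploid NPC libraries, 1 point per library. POU5F1 is at 1859 FPKM in diploid ESCs, 1332 FPKM in haploid ESCs and 1.5 FPKM in NPCs, and SNURF at 473, 0.82 and 166 FPKM.

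Imprinted genes that are expressed from the paternal allele went both ways between haploid and diploid ESCs. Of 16 measured, 3 were at least 4-fold lower in haploid ESCs and 3 at least 4-fold higher, with a median of 0.14 at percentile 72.5. With a pseudocount of 0.1 in place of 1, a count chosen after seeing the data, MAGEL2, IGF2 and ZDBF2 also passed 4-fold, so that 6 were lower and 3 higher. SNURF, NDN and NNAT were the lower ones, NDN standing at 8.71 FPKM in diploid ESCs, 0.69 FPKM in haploid ESCs and 40.3 FPKM in NPCs, and NNAT at 13.7, 2.18 and 0.47 FPKM. MAGEL2 was at 2.48, 0.01 and 2.41 FPKM. PEG3, PLAGL1 and NAP1L5 were the higher ones, each below 1 FPKM in diploid ESCs. PEG3 stood at 0.03 FPKM in diploid ESCs, 10.2 FPKM in haploid ESCs and 0.01 FPKM in NPCs, and PLAGL1 at 0.5, 9.3 and 5.55 FPKM. Of the 12 measured genes expressed from the maternal allele, TFPI2 was at least 4-fold lower in haploid ESCs, at 10.5 and 1.83 FPKM, and the median was -0.24 at percentile 9.5. H19 stood at 4.03 FPKM in diploid and 6.44 FPKM in haploid ESCs, and IGF2 at 10.3 and 1.97 FPKM. XIST was not analysed here.

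Genes were also grouped by chromosome, taken from the T2T-MMU8v2.0 assembly. Genes of the X chromosome were higher in haploid ESCs, with a median log2 ratio of 0.60 over 529 genes, 75.2% of which had a ratio above 0. The medians of the 20 autosomes ran from -0.28 on chromosome 19 to 0.21 on chromosome 5. Between NPCs and diploid ESCs the X median was -0.10, within the autosomal range of -0.21 to 0.14.

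**Figure D3:**
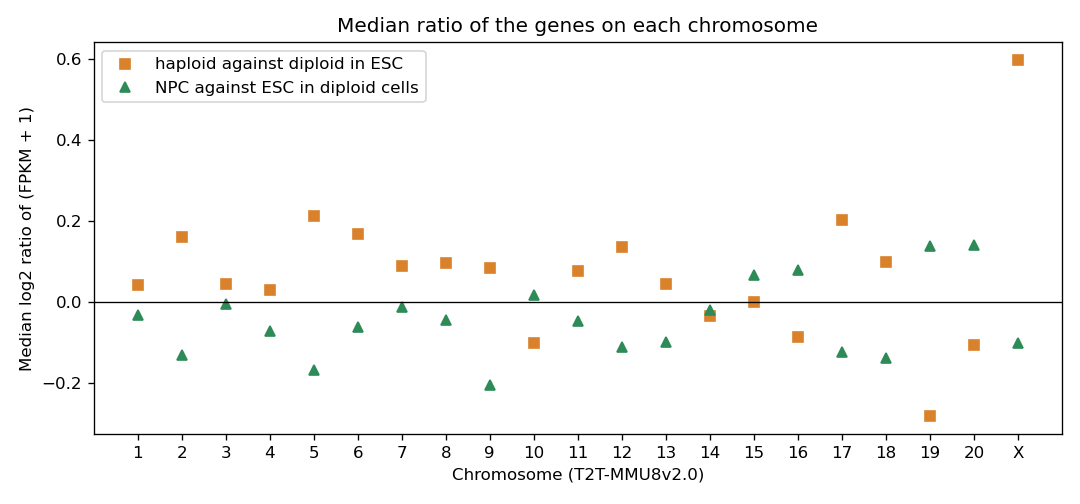
Median log2 ratio of FPKM plus 1 over the genes of each chromosome, for haploid against diploid ESCs (squares) and diploid NPCs against diploid ESCs (triangles), with 1 library per group. The X chromosome is at 0.60 in the first comparison, above the highest autosome at 0.21, and at -0.10 in the other.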

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

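No median of a list outside the central 95% of random lists changed sign under any alternative run, and no named ratio of at least 2-fold did with another pseudocount, TMM factors or TPM rescaling. A value is described as moved when it changed by over 1.5-fold, or by over 0.1 for a correlation. TMM factors moved no count, list median or named ratio, whereas 104 of 270 named ratios moved with a pseudocount of 0.1 and 43 with TPM rescaling. With a pseudocount of 0.1, counts of genes past 4-fold were 1817 higher and 1526 lower in NPCs, and 330 higher and 728 lower in haploid ESCs, and NPC list medians were -6.58 (pluripotency), 6.94 (midbrain), 3.81 (hindbrain), -4.87 (endoderm), -4.92 (epithelial) and -5.53 (Nodal); a smaller pseudocount widens the ratios of low genes by construction. A threshold of 2-fold gave 3287 and 2842 genes in NPCs and 1041 and 1329 in haploid ESCs, and 8-fold gave 306 and 311, and 41 and 110. Genes with a symbol alone gave 772 higher in NPCs and 89 higher in haploid ESCs, from fewer genes. A mean of at least 5 FPKM gave 80 higher and 218 lower in haploid ESCs, NPC medians of 0.34 (neural progenitor), 4.14 (hindbrain), 2.74 (neuron) and -5.04 (epithelial), haploid ESC medians of 1.27 (fibroblast) and 1.08 (Notch), and r = 0.548 between haploid ESCs and NPCs. Without a filter, the counts cannot change, since genes below the filter cannot reach 4-fold at a pseudocount of 1; NPC medians were 0.94 (neural progenitor), 0.14 (midbrain), 1.06 (hindbrain) and -2.14 (endoderm), the haploid ESC medians were -2.37 (endoderm), -0.35 (neural crest) and -0.25 (trophectoderm and amnion), and r was 0.864 between diploid ESCs and NPCs and 0.831 between haploid ESCs and NPCs. TPM rescaling gave 291 genes higher in haploid ESCs and moved the median ratio of all genes there from 0.02 to 0.21, so ratios near 0 in that comparison carry no direction. Against haploid in place of diploid ESCs, chosen after seeing the data, 1676 genes were higher and 1143 lower in NPCs, of which 1025 and 515 also passed against diploid ESCs, and medians were -4.80 (pluripotency), 0.072 (neural progenitor), 2.32 (neuron), -0.31 (endoderm), -0.55 (epithelial), -0.96 (endoplasmic reticulum stress) and -0.29 (hypoxia and glycolysis). Of 135 named NPC ratios, 76 moved and 19 more of at least 2-fold changed sign against haploid ESCs. Those lower against diploid ESCs were then ADM (2.04), CXCR4 (1.13), CYP26A1 (3.49), DDIT3 (0.091), DDIT4 (1.48), DPRX (0.34), FOXA2 (0.71), HHEX (3.18), KLF5 (0.85), KRT19 (1.36), LGR5 (0.27), RBFOX3 (0.24), SNURF (6.52), SPP1 (2.17), TFPI2 (1.01) and TRIB3 (0.17), and those higher were NAP1L5 (-0.36), PLAGL1 (-0.65) and ZEB2 (-0.44). With a pseudocount of 0.1, chosen for this count after seeing the data, 6 in place of 3 paternally expressed genes were at least 4-fold lower in haploid ESCs and 3 higher. With random lists matched on gene length too, also chosen then, 11 in place of 13 lists lay outside the central 95% in haploid ESCs, without mesoderm and mesenchymal genes, and 18 in place of 17 in NPCs, with housekeeping genes. Where no cause is named, the cause was not tested. Alternatives of results that need haploid NPCs were not run. No paired analysis was possible because each group holds 1 library. Depth limits low genes most in the NPC library, at 78.5% of the depth of diploid ESCs.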

Other observations

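Some single genes, chosen after their values were seen, differed between the libraries, although the Notch, DNA methylation, Wnt, p53 target and spindle lists as a whole lay inside the range of random lists in both comparisons. NOTCH1 also belongs to the neural progenitor list and DNMT3B to the pluripotency list. NOTCH1 stood at 7.56 FPKM in diploid and 17.1 FPKM in haploid ESCs, NOTCH2 at 5.04 and 14.3 FPKM, NOTCH3 at 12.6 and 35.7 FPKM and the ligand JAG1 at 7.75 and 17.5 FPKM. The ligand DLL1 went the other way, at 4.38 and 0.9 FPKM, and 5 of the 10 measured Notch genes were lower in haploid ESCs, with a list median log2 ratio of 0.11 at percentile 58.9. Of the DNA methylation genes, DNMT3B was lower in haploid ESCs, at 391 and 109 FPKM, and UHRF1 higher, at 15.8 and 56.7 FPKM. LGR5 stood at 19.9 FPKM in diploid ESCs, 0.42 FPKM in haploid ESCs and 0.71 FPKM in NPCs, and FZD5 at 55.1, 12.8 and 0.4 FPKM. Among p53 targets, CDKN1A was at 6.18 FPKM in diploid ESCs, 2.26 FPKM in haploid ESCs and 36.6 FPKM in NPCs, and MDM2 at 4.73, 14.7 and 0.86 FPKM. The spindle and centrosome list had a median of 0.41 in haploid against diploid ESCs, at percentile 96.1, with ASPM at 3.38 and 13.0 FPKM and WDR62 at 23.7 and 11.2 FPKM.

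Tests of the patterns below were chosen after the result was seen, except those on gene length and on the additional list of definitive endoderm genes, whose outcomes had not been examined.

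X-linked genes had a median log2 ratio of 0.60 in haploid against diploid ESCs. A trend with gene length does not account for it: ratios were higher for longer genes across all genes (Spearman rho 0.281), yet X genes lay 0.58 above random gene sets matched on expression and length. A candidate explanation is dosage: 1 active X for 1 set of autosomes in haploid cells, and 1 active X for 2 sets in diploid cells. Taken simply, it would put X genes 2-fold above autosomes, while their excess over the autosomal median was 1.49-fold. That excess is on FPKM plus 1, which understates differences of genes with low values. Its distance from 2-fold is therefore no evidence against dosage. Under dosage, genes that escape X inactivation should be raised less if the diploid line has a second, inactive X. The sex of the lines is not given in the sources used here, and the Y-linked list, with 2 of 7 genes measured, does not settle it. KDM5D, UTY, USP9Y and ZFY were below 1 FPKM in every library used, which gives no sign of a Y chromosome. How these genes would read in a line with a Y was not tested. DDX3Y was expressed at a similar level in both ESC libraries. Haploid cells carry a single set of chromosomes, and X genes were expressed in the haploid library. DDX3Y there cannot be read as a mark of a Y, and its similar level in diploid ESCs is no evidence of a Y either. The 24 measured escape genes had a median of 0.25, a difference of -0.39 from the other X genes, with a bootstrap 95% interval of -0.74 to -0.21. That interval resamples genes without matching on expression and holds no variation between libraries or lines. Among X gene sets matched on expression, the escape genes lay at percentile 2.86, short of the 2.5 set as the limit. A form of this test without KDM6A, an escape gene already seen to be higher in haploid ESCs, gave -0.40 and percentile 3.41. Dosage stays open, as do a trend with GC content, which was not tested, and a difference between the cell lines, which 1 library per group cannot separate from ploidy.

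SNURF, NDN and MAGEL2, neighbours that are expressed from the paternal allele, were near 0 in haploid ESCs and present in both diploid libraries. Haploid cells have a single parental genome, so a candidate explanation is that all paternally expressed genes are silent in a maternal genome. Of 16 measured genes, 3 were at least 4-fold lower and 3 at least 4-fold higher. With a pseudocount of 0.1, chosen after seeing the data, 6 were lower and 3 higher. The number of lower genes does not decide it. Genes below 1 FPKM in diploid ESCs, as the higher ones were, cannot be 4-fold lower on FPKM plus 1. The higher genes were expressed in haploid ESCs, PEG3 at 10.2 FPKM, PLAGL1 at 9.3 FPKM and NAP1L5 at 5.66 FPKM. That argues against silence of all genes of the list in this library. Members expressed in both ESC libraries argue against it too, as far as values per gene can show. MEST stood at 49.4 FPKM in diploid and 78.9 FPKM in haploid ESCs, INPP5F at 42 and 109.8 FPKM, DLK1 at 4.69 and 9.7 FPKM and SGCE at 4.79 and 6.37 FPKM. All these values are per gene, so they do not tell an imprinted transcript from any other transcript of the same gene. Loss or silence of all 20 nearest measured genes is argued against too, since their median ratio was 0.30. UBE3A among them stood at 22.5 FPKM in diploid and 31.9 FPKM in haploid ESCs. The 2 of them that were at least 4-fold lower were LOC106999081, at 17.7 and 0.31 FPKM, and LOC106996620, at 13.3 and 0.04 FPKM. LOC106999080 stood at 1.44 and 0 FPKM, too low in diploid ESCs to reach 4-fold on FPKM plus 1. Loss or silence of a smaller block around SNURF, NDN and MAGEL2 therefore stays open. Silence of the paternally expressed genes at this locus, with imprints lost at some other genes, stays open and was not tested. The locus was not the only one with lower values. NNAT, at 13.7 and 2.18 FPKM, and IGF2, at 10.3 and 1.97 FPKM, were lower in haploid ESCs and are not among the 20 nearest genes. Of the 16 measured genes, 8 were lower to any degree and 8 higher. The parental origin of the haploid genome is not given in the sources used here.

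Endoderm markers were lower in haploid than in diploid ESCs, and a candidate explanation is that definitive endoderm cells were present in the diploid ESC culture. An additional list of 18 definitive endoderm genes, none of them in the other lists, had 12 measured members. Their median ratio was -1.08, at percentile 0.03 of random lists, the direction that such cells would give. These members did not all move together: KRT19, at 81.9 and 2.71 FPKM, HAS2, at 62.6 and 8.57 FPKM, and LHX1, at 32.2 and 5.78 FPKM, were lower in haploid ESCs, whereas 5 of the 12 were higher, NTN4 standing at 5.39 and 20.1 FPKM. The median also depends on the filter: ERBB4, DKK4, APOB, SERPINA1 and DENND2C, below a mean of 1 FPKM, had ratios of 0.03, 0.46, 0.18, 0.07 and -0.90. Differentiation into other lineages stays open: the trophectoderm and amnion, neural crest and mesoderm lists had medians of -1.33, -1.14 and -0.78, at percentiles 0.14, 0.28 and 2.26 (6.14 for mesoderm among lists matched on gene length too). The trophectoderm and amnion and the neural crest medians were much smaller in size without a filter, as given above. The neuron list had a median of 0.20, with 8 members higher and 7 lower. It decides nothing by the limits set, since 3 of its members were at least 2-fold lower although its median was above 0. An effect of ploidy itself on endoderm genes stays open, since each group holds 1 library.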
